A study of Mus musculus with 12 samples.

How the data were processed

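Total RNA from the micro-dissected medial prefrontal cortex of 6 control and 6 poly(I:C) offspring was extracted with a Qiagen AllPrep kit and measured on Affymetrix GeneAtlas strips of the Mouse Gene 1.1 ST design, per the labels' protocols, which give 250 ng RNA as input and name both 3' IVT and whole-transcript kits without saying which was used. The deposited values are log2 expression per probe set, per the scale of the values (from about 2 to 12 with nearly equal array medians). RMA and Partek 6.6 are named in the submitters' processing notes without their role or order. The annotation and genome build behind the values are not given in the sources used here, and no coordinates are printed. Background correction and quantile normalization of the kind RMA performs would compress small differences near the floor and make array distributions alike. The number of arrays limits the precision.

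The value table held 35556 probe sets in 12 columns, all of which were used. Probe sets were named from the platform annotation, which can be old. Of them 21218 carried 1 gene symbol, 1881 several and 12457 none, and 21185 of the single symbols were matched through their gene identifier to the RefSeq gene table of GRCm38.p6, which served only for names and for finding which genes lie between Dlk1 and Dio3. The 23099 probe sets with at least 1 gene were tested, none was named where several genes shared it, and the 21218 stand for 18820 distinct symbols.

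Groups were compared as poly(I:C) minus control with lmFit and eBayes in limma 3.58.1 (R 4.3.3), without covariates, two-sided, with Benjamini-Hochberg adjustment over the 23099 probe sets. Errors of log2 differences are the moderated standard errors (SE) of that fit, and adjusted p-values of single genes come from it. A second, descriptive criterion was an unadjusted p under 0.05 with at least 1.2-fold. For gene lists, the mean over member genes, each by its brightest single-gene probe set, gave 1 score per sample, and the difference of group means was tested with an exact permutation test over all 924 splits, two-sided, adjusted over the 28 lists. The lists covered oligodendrocyte stages, other brain cell types, neighbouring tissue, cortical layers, immune response, receptors, synapses, metabolism, stress and the clock. These lists, the tests and the alternatives were set before the data were examined. The rule for named genes was also set then: the 12 largest increases and 12 largest decreases among single-gene probe sets past the adjusted threshold, up to 4 members of each list with the lowest p, the myelin genes Mbp, Mobp, Mag, Mog and Cnp with a further one that is not reported here, and the sex-linked genes. The text gives the most relevant of the list members.

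After the data had been seen, 7 lists were added and adjusted among themselves: small nucleolar RNAs, ribosomal proteins, Dlk1-Dio3 transcripts, microRNAs outside that locus, hosts of small nucleolar RNAs, olfactory and vomeronasal receptors, and genes known for detained introns. The last was typed before its values were computed, leaving out genes already seen among the largest changes. Gene sets were also tested with camera, with preset and estimated correlation, and with fry, which tests whether a set's genes move on balance one way and does not compare the set with other genes.

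Alternatives comprised the replicate number as a block, array weights, quantile normalization, median centring, brightness filters at the 25th and 50th percentile, all rows of the table, eBayes with trend and robust, no moderation, other summaries of the lists, and leaving out each sample in turn. Added later were the removal of controls 5 and 6 together and the striatal, deep-layer and detained-intron scores as covariates. Correlations were computed in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1 on scores centred within groups, with 100000 permutations within groups, and plots were drawn with matplotlib 3.10.9. The fit was tested on simulated data drawn independently for each of the 23099 probe sets from the real means and spreads, 6 against 6, with 200 probe sets shifted: it recovered 78% of log2 shifts of 0.25 and 100% of shifts of 0.5 with 11 false calls, and made 0 calls with no shift. In 500 random lists of 20 genes, made from the real deviations from group means with samples shuffled, the list test gave p under 0.05 in 4.4% without a shift and in 99.8% with a log2 shift of 0.1. Random genes need not move together as members of real lists do, whose correlation was estimated at 0.56 for myelin and 0.50 for striatal markers. The simulated p-values were also not adjusted over lists, so the 99.8% does not carry over to the lists reported here. Likewise, the simulated probe sets were drawn independently, so the number of false calls need not carry over to real probe sets, which can vary together.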

Results

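Gene expression was measured in the medial prefrontal cortex of adult C57BL/6 mice, aged 12 weeks, whose mothers had been injected during late pregnancy. The mothers received poly(I:C), a synthetic double-stranded RNA that sets off an antiviral immune response, at 5 mg/kg intravenously on gestation day 17, or saline. The series held 6 control offspring and 6 poly(I:C) offspring, with 1 array for each animal, and the comparison asks how prenatal immune activation alters cortical expression in adulthood. The titles call the samples biological replicates. The labels used here name neither litter nor sex nor array strip, and p-values measure the spread between these animals, some of which may be littermates. In the labels the control samples carry numbers from 1 to 12 and the poly(I:C) samples numbers from 25 to 33, and whether the arrays were run in that order is not given in the sources used here. Array medians lay between 5.15 and 5.21 on the log2 scale, and pairs of arrays correlated at r = 0.994 to 0.998 across genes, which are not independent replicates. The first principal component held 24.3% of the variance and separated the groups (exact permutation p = 0.0022, two-sided, the smallest that 924 splits can give). The second (13.4%) and the third (11.3%) did not (exact permutation p = 0.98 and 0.69).

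In offspring of poly(I:C)-treated mothers, 17 of 59 small nucleolar RNAs, which guide modification of ribosomal RNA, were lower past the adjusted threshold, 14 of them of the box C/D class, and 2 were higher, and 9 of 33 myelin markers were lower. Of 40 transcripts of the imprinted Dlk1-Dio3 locus, a cluster of maternally expressed noncoding RNAs and microRNAs, 18 were higher and 22 did not pass. Both RNA classes were singled out after the data had been seen, and neither list passed in camera with an estimated correlation (adjusted p = 0.070 for both). The largest decrease was that of Snord73b (probe set 10499130), from 7.60 ± 0.29 in controls to 6.21 ± 0.51 after poly(I:C) (log2, SD, n = 6 each), a 2.61-fold fall. Among probe sets of a single gene past the adjusted threshold, the largest increase was that of Rian (probe set 10398360), a long noncoding RNA of the Dlk1-Dio3 locus, from 5.28 ± 0.30 to 5.90 ± 0.23, or 1.53-fold. Most changes were small, with a median absolute log2 difference of 0.19 among those past the threshold.

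In the limma fit, 653 of 23099 annotated probe sets differed at an adjusted p under 0.05, of which 467 were higher and 186 lower after poly(I:C). Of these, 594 carried exactly 1 gene, standing for 391 genes that were higher, 156 that were lower and 1, Ahctf1, with probe sets called in both directions. At least a 1.2-fold change was reached by 139 of the 653. By the descriptive criterion of an unadjusted p under 0.05 and at least 1.2-fold, 190 probe sets differed, 115 higher and 75 lower. At an unadjusted p under 0.05 alone, 4401 probe sets passed where 1155 would by chance. The groups did not overlap in 547 probe sets, or 2.37%, against 0.216% by chance. The split between directions depended on scaling: it was 239 higher and 285 lower after quantile normalization and 298 higher and 232 lower after centring each array on its median, against 467 and 186 as deposited. Leaving out 1 animal gave 230 calls without control 2, 281 without control 3, 331 without control 1, 236 without poly(I:C) 1, 302 without poly(I:C) 4, 392 without poly(I:C) 6 and 396 without poly(I:C) 3, and the most, 818, without poly(I:C) 2.

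The 12 genes with the largest increases held 5 from the Dlk1-Dio3 locus. Besides Rian these were the microRNA genes Mir382 (log2 difference 0.61 ± 0.12 SE), Mir679 (0.50 ± 0.11), Mir300 (0.47 ± 0.11) and Mir376b (0.46 ± 0.11). Mir300 and Mir376b were dim, with control means of 3.70 and 4.11, near the 25th percentiles of the arrays (3.92 to 3.96). Mir128-1, a microRNA gene outside the locus, was 0.60 ± 0.07 higher with no overlap between groups (adjusted p = 0.00066). The others were Cox20, an assembly factor of cytochrome c oxidase (0.55 ± 0.11), Uggt2, a glucosyltransferase of glycoprotein folding (0.47 ± 0.08), Cdr1os, the noncoding transcript of the Cdr1 locus (0.46 ± 0.08), Rskr (0.58 ± 0.10), Leng8 (0.46 ± 0.10) and the clone 4930578G10Rik (0.59 ± 0.12). The other probe set of Cox20 differed by -0.06. The calls of Mir376b, Mir300, Mir679 and Leng8 were each lost without control 1, control 2, control 3, poly(I:C) 1 or poly(I:C) 6, with adjusted p up to 0.0931 for Mir376b, 0.0739 for Mir300, 0.0705 for Mir679 and 0.0671 for Leng8. Mir376b, Mir679 and Leng8 were lost without poly(I:C) 4 too (adjusted p = 0.0886, 0.0506 and 0.0577), and Mir376b without control 6 (0.0638).

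Among the 12 largest decreases, 8 were small nucleolar RNA genes. After Snord73b came Snord47 (-1.05 ± 0.18), Snord33 (-0.86 ± 0.09), Snord87 (-0.82 ± 0.12), Snord49a (-0.80 ± 0.14), Snord82 (-0.74 ± 0.10), Snord35b (-0.65 ± 0.08) and Snord104 (-0.61 ± 0.11). Gas5, a spliced RNA whose introns host several box C/D RNAs, was lower on 1 probe set (-0.78 ± 0.08, adjusted p = 0.00052), while its other 3 probe sets differed by 0.13, 0.22 and 0.08 and did not pass. Rny1, a small noncoding Y RNA, differed by -0.64 ± 0.15, a call lost without control 1, control 2, control 3, control 6, poly(I:C) 1 or poly(I:C) 3 (adjusted p up to 0.0735). The remaining 2 were Thbs4, an extracellular matrix thrombospondin (-0.54 ± 0.10), and Mobp, a structural protein of myelin (-0.50 ± 0.09).

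Both RNA classes were then scored as lists defined after the data had been seen, together with 5 others, so their tests are not independent of the genes above. Of 40 Dlk1-Dio3 transcripts measured, 18 rose and 22 did not pass, and the mean rose by 0.25, from 4.89 ± 0.09 to 5.14 ± 0.13 (log2, SD, n = 6; exact permutation p = 0.0043, adjusted over 7 lists 0.015), with 6 of 6 poly(I:C) samples above the control mean. Meg3, the long noncoding RNA at the start of the cluster, singled out after its values were seen, was 0.39 ± 0.09 higher. Of 59 small nucleolar RNAs, 17 fell, 2 rose and 40 did not pass, and the mean fell by 0.19, from 5.77 ± 0.10 to 5.58 ± 0.07 (log2, SD, n = 6; exact permutation p = 0.0087, adjusted 0.020), with 6 of 6 poly(I:C) samples below the control mean. Of the 17, 14 were among the 30 box C/D RNAs, a class looked at after the fall had been seen (difference -0.29, 1 higher), and 3 among the 26 H/ACA RNAs (-0.077, exact permutation p = 0.37, 1 higher). Control 5 lay at 5.57, within the range of the poly(I:C) samples. In camera with an estimated correlation neither list passed (adjusted p = 0.070 for both). The number of Dlk1-Dio3 calls was 8 without control 1 or control 2, 7 without control 3 or poly(I:C) 1, and 9 without poly(I:C) 4 or poly(I:C) 6. Without variance moderation 1 Dlk1-Dio3 transcript and 9 small nucleolar RNAs passed, with 25 and 26 at an unadjusted p under 0.05, and among members at or above the 50th percentile of brightness 7 of 12 and 12 of 26 passed. The labelling kit actually used is not given in the sources used here, and it bears on whether probe sets of small nucleolar RNAs and microRNAs measured the short RNAs themselves or longer transcripts that contain them.

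Transcripts known for detained introns, which stay in the nucleus incompletely spliced, were scored in the same way. All 26 measured members of this list, also set up after the data had been seen, had higher means after poly(I:C), 7 of them past the threshold, and the list mean rose from 7.63 ± 0.07 to 7.78 ± 0.07 (log2, SD, n = 6; exact permutation p = 0.0022, adjusted 0.015; adjusted p = 0.070 in camera with an estimated correlation). With the score of this list as a covariate no probe set passed in limma, against 653 without it, and 1552 had an unadjusted p under 0.05. The score did not overlap between groups (highest control 7.721, lowest poly(I:C) 7.724). Such a covariate takes up much of any group difference, so this fit does not show that the changes follow the score. The number of its members called was 2 without control 2, control 3 or poly(I:C) 1, 3 without control 1, poly(I:C) 4 or poly(I:C) 6, 12 without control 5, 4 after quantile normalization and 13 of 25 at or above the 50th percentile of brightness. Without variance moderation in limma it was 0, with 19 members at an unadjusted p under 0.05.

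**Figure D1:**
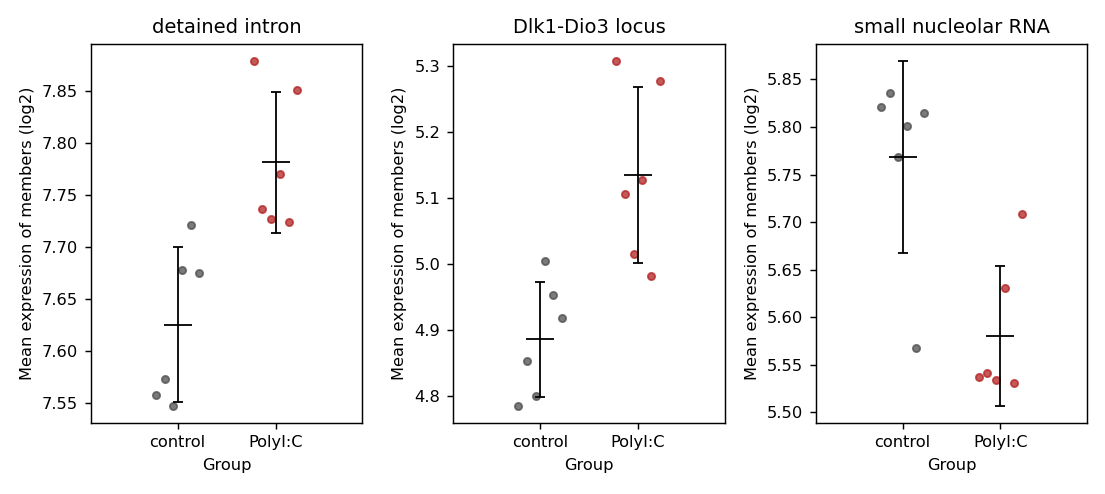
Mean log2 expression of the members of the detained intron, Dlk1-Dio3 and small nucleolar RNA lists (26, 40 and 59 genes) in each of the 6 control (grey) and 6 poly(I:C) (red) samples, with bars for the group mean ± SD. The first and second lie higher after poly(I:C), by 0.16 and 0.25, and the third lies lower, with control 5 at 5.57 apart from the other controls.

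Of 33 measured markers of myelin and mature oligodendrocytes, 9 fell, none rose and 24 did not pass over all probe sets, and 31 of the 33 had a lower mean. Cldn11, the tight-junction protein of myelin, fell from 8.35 ± 0.10 to 7.91 ± 0.21 (log2, SD, n = 6 each; 1.36-fold; limma adjusted p = 0.011). Mobp (probe set 10590269) fell from 8.70 ± 0.14 to 8.20 ± 0.24 (1.42-fold; adjusted p = 0.012), and neither gene's groups overlapped. Cnp, a phosphodiesterase of oligodendrocytes, differed by -0.34 ± 0.07 (SE; adjusted p = 0.023), and Adamts4, a secreted protease, by -0.33 ± 0.07 (adjusted p = 0.022). Both calls were lost without control 2, control 3 or poly(I:C) 1, with adjusted p up to 0.061 for Cnp and 0.0584 for Adamts4. The 5 further calls, named after their values were seen, were Myrf, the transcription factor that drives myelin genes (log2 difference -0.30 ± 0.06 SE), the membrane proteins Mal (-0.39 ± 0.09) and Tspan2 (-0.31 ± 0.08), the connexin gene Gjb1 (-0.22 ± 0.05) and transferrin, Trf (-0.30 ± 0.08). Mag and Mog, surface glycoproteins of myelin, differed by -0.33 ± 0.09 and -0.32 ± 0.09 and did not pass (adjusted p = 0.052 and 0.074). Mag passed without poly(I:C) 5 or poly(I:C) 6 (adjusted p = 0.0371 and 0.0381), after quantile normalization (0.0404), with median centring (0.0444) and with array weights (0.0411), and Mog passed without poly(I:C) 5 (0.0321). Mbp was measured only by a probe set shared with another gene, so no value is given for it.

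As a list, the myelin markers differed by -0.22, with means of 7.06 ± 0.09 in controls and 6.84 ± 0.14 after poly(I:C) (SD, n = 6), and 6 of 6 poly(I:C) samples lay below the control mean. The exact permutation test gave p = 0.011, which did not pass after adjustment over 28 lists (adjusted p = 0.081). Camera with its preset correlation called the list (adjusted p = 3.6e-16), and the call was lost with an estimated correlation (adjusted p = 0.28). Adjusted over the list alone, 21 members were lower. The study is known to have examined myelin genes in these animals, so neither this count nor the direction is independent evidence. The number of members called was 2 without control 2 or poly(I:C) 1, 3 without control 3, 4 without poly(I:C) 4 and 14 without poly(I:C) 5. Without variance moderation in limma it was 0, with 18 members at an unadjusted p under 0.05.

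**Figure D2:**
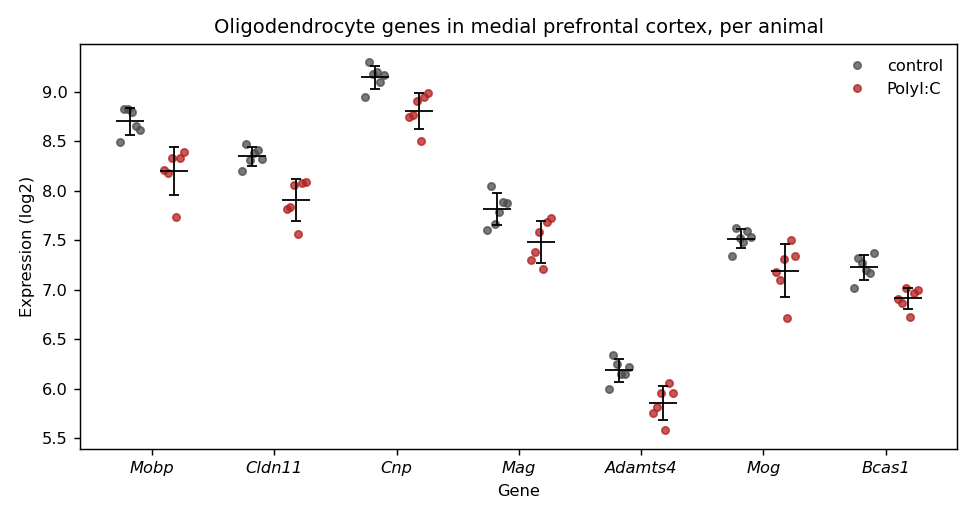
Log2 expression of 7 oligodendrocyte genes in each of the 6 control (grey) and 6 poly(I:C) (red) samples, with bars for the group mean ± SD. Every gene has a lower mean after poly(I:C); the groups do not overlap for Mobp, Cldn11 and Bcas1, and Mag and Mog did not pass the adjusted threshold.

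Earlier stages of the lineage gave smaller differences. Among 13 markers of newly formed oligodendrocytes, Bcas1 fell (-0.31 ± 0.06, adjusted p = 0.013, no overlap) and 12 did not pass, with Enpp6 at -0.16 ± 0.05, Tcf7l2 at -0.11 ± 0.04 and Tmem163 at -0.09 ± 0.05. The list differed by -0.049, with 6 of 6 poly(I:C) samples below the control mean (exact permutation p = 0.0087, adjusted 0.081). Among 14 markers of oligodendrocyte precursors, Pcdh15 rose (0.22 ± 0.05, adjusted p = 0.022), a call lost without control 2 or poly(I:C) 1 (adjusted p up to 0.0582), and 13 did not pass, C1ql1 being at -0.12 ± 0.04. Enpp6 passed without control 4 (adjusted p = 0.0429) and C1ql1 after quantile normalization (0.0464). The precursor list differed by -0.0056 (exact permutation p = 0.77), and its difference was above 0 without control 2, control 5, poly(I:C) 2 or poly(I:C) 3. Cholesterol synthesis genes, on which myelin formation draws, differed by 0.013 as a list of 20 (exact permutation p = 0.72), with Mvd at -0.14 ± 0.04 and Hsd17b7 at 0.14 ± 0.06, none called. That list mean was below 0 after quantile normalization and without control 4 or poly(I:C) 3, and Mvd passed without control 4 (adjusted p = 0.0211).

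Markers of neighbouring tissue and of cortical layers were scored too, and none of these lists passed after adjustment. All 15 measured striatal markers had lower means after poly(I:C). Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor of striatal neurons, fell (-0.27 ± 0.06, adjusted p = 0.028), and 14 did not pass, including Drd2 (-0.54 ± 0.17, adjusted p = 0.098), Gpr6 (-0.49 ± 0.13, adjusted p = 0.059) and Isl1 (-0.13 ± 0.04). The striatal list differed by -0.23, from 6.13 ± 0.21 to 5.90 ± 0.04 (SD, n = 6; exact permutation p = 0.015, adjusted 0.081), and controls 5 and 6 had its highest scores, 6.45 and 6.32. Its call in camera with the preset correlation (adjusted p = 3.1e-08) was lost with an estimated correlation (adjusted p = 0.28). Without those 2 animals, an alternative chosen after seeing the data, the striatal difference was -0.10 and the myelin difference -0.20, 627 probe sets passed, and Ppp1r1b did not. Ppp1r1b was also lost without control 2, control 6, poly(I:C) 1, poly(I:C) 3 or poly(I:C) 4 (adjusted p up to 0.0674). Gpr6 passed without control 4 (0.0373) and with array weights (0.0473), and Isl1 and Drd2 passed without control 1 (0.0471 and 0.0431).

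Among 17 deep-layer markers, Bcl11b, a transcription factor of subcortically projecting neurons, fell (-0.16 ± 0.04, adjusted p = 0.040), a call kept in the fits without control 4, poly(I:C) 2 or poly(I:C) 5 and lost without any other single animal (adjusted p up to 0.0952). The Bcl11b call was also lost without controls 5 and 6 together, the animals with the highest striatal scores (-0.15, limma adjusted p = 0.0928). Cplx3 (-0.21 ± 0.06), Ccn2 (-0.26 ± 0.08) and Ntsr1 (-0.20 ± 0.06) did not pass. The deep-layer list differed by -0.089 (exact permutation p = 0.058, adjusted 0.16), and with its score as a covariate 48 probe sets passed instead of 653. Of 14 upper-layer markers none passed, with Calb1 at 0.13 ± 0.04, Rorb at 0.13 ± 0.04, Inhba at 0.25 ± 0.08 and Rasgrf2 at 0.14 ± 0.05, and the list differed by 0.077, with 6 of 6 poly(I:C) samples above the control mean (exact permutation p = 0.017, adjusted 0.081). Camera with the preset correlation called both layer lists, and with an estimated correlation neither (adjusted p = 0.42 for deep and 0.28 for upper layers). After quantile normalization and after median centring the upper-layer difference was smaller, at 0.051 and 0.066 (exact permutation p = 0.089 and 0.087), and the deep-layer difference larger, at -0.11 and -0.10 (0.017 and 0.043, neither passing after adjustment). Single members passed when an animal was left out: Cplx3 and Calb1 without control 5 (adjusted p = 0.0435 and 0.0457), Ccn2 and Rasgrf2 without poly(I:C) 5 (0.0311 and 0.0288) and Inhba without poly(I:C) 2 (0.0440), and Cplx3 also after median centring (0.0461).

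**Figure D3:**
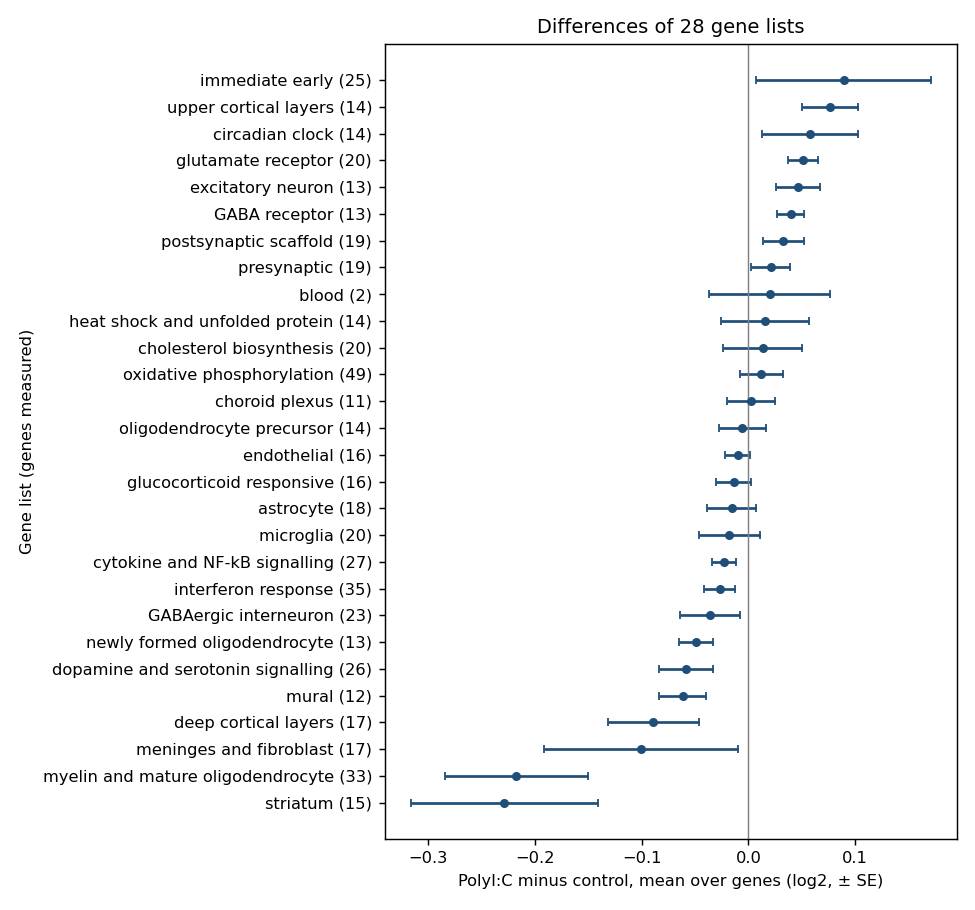
Difference of the mean log2 expression of each of 28 gene lists, poly(I:C) minus control, with the number of genes measured in parentheses, points for the difference and bars for ± 1 SE from the 6 samples of each group. The striatal and myelin lists lie lowest, at -0.23 and -0.22, and no list passed after adjustment over the 28.

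Among markers of other cells no member passed in limma. The list differences were -0.016 for 18 astrocyte genes (exact permutation p = 0.52), -0.018 for 20 microglial genes (0.53), -0.010 for 16 endothelial genes (0.41), -0.062 for 12 mural cell genes (0.024, adjusted 0.095), -0.10 for 17 genes of meninges and fibroblasts (0.28), 0.0026 for 11 choroid plexus genes (0.92) and 0.020 for 2 blood genes (0.72). An unadjusted p under 0.05 was reached by 3 mural genes, 2 of meninges and fibroblasts, 1 endothelial and 1 choroid plexus gene and by 0 astrocyte, microglial and blood genes. Quantile normalization made the first 3 differences larger, at -0.043 for astrocyte (exact permutation p = 0.041), -0.045 for microglial (0.11) and -0.034 for endothelial genes (0.028), none passing after adjustment, and median centring gave -0.026, -0.028 and -0.021 (0.38, 0.35 and 0.32). Without control 6 the meninges difference was -0.17 (exact permutation p = 0.030), and without poly(I:C) 4 the endothelial difference was -0.020 (0.043), neither passing after adjustment. Camera with the preset correlation called the mural and the meninges lists, and with an estimated correlation neither (adjusted p = 0.28 and 0.61). The median member was at 0.0017 for endothelial and -0.012 for choroid plexus genes, opposite in sign to the means, the choroid plexus mean was also below 0 after median centring and without control 4, control 6, poly(I:C) 1 or poly(I:C) 4, and the blood mean was below 0 without poly(I:C) 4. Both were below 0 without controls 5 and 6. Among the members with the lowest p were the astrocyte gene Gfap (-0.20 ± 0.13), the microglial genes Siglech (0.07 ± 0.03) and C1qc (-0.08 ± 0.04), the endothelial gene Tie1 (-0.13 ± 0.04) and the mural genes Vtn (-0.14 ± 0.04, adjusted p = 0.052) and Acta2 (-0.24 ± 0.11). Tie1 passed without control 5 (adjusted p = 0.0317), and Vtn passed without control 4 or control 6 (0.0401 and 0.0358) and after quantile normalization (0.0214).

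No gene of the immune lists passed in limma. Of 35 interferon-response genes, 3 had an unadjusted p under 0.05: Ddx58, an RNA sensor (-0.10 ± 0.03), Mx1 (-0.11 ± 0.05) and Stat2 (0.07 ± 0.03). Their list differed by -0.027 (exact permutation p = 0.091, adjusted 0.21). Of 27 cytokine and NF-kB genes, 1 had an unadjusted p under 0.05, the receptor gene Tnfrsf1a (-0.11 ± 0.04), and the list differed by -0.023 (exact permutation p = 0.082, adjusted 0.21). Neither list was called by camera or fry. The control means were 5.20 for the interferon and 4.72 for the cytokine list, near and below the array medians (5.15 to 5.21). Changes of dim members could therefore have been missed.

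Neurotransmitter receptor genes were examined by class. Of 20 glutamate receptor genes, Gria4, an AMPA receptor subunit, rose (0.19 ± 0.04, adjusted p = 0.022, no overlap) and 19 did not pass, among them Gria3 (0.10 ± 0.03), Grm7 (0.14 ± 0.04) and Grin2a (0.14 ± 0.05). Grm7 passed without poly(I:C) 5 (adjusted p = 0.0278) and Grin2a without control 4 (0.0497). Adjusted over the list alone, 7 were higher. The list differed by 0.051, with 6 of 6 poly(I:C) samples above the control mean (exact permutation p = 0.0065, adjusted 0.081). GABA receptor genes differed by 0.040 over 13 members, with 5 of 6 poly(I:C) samples above the control mean (exact permutation p = 0.013, adjusted 0.081), with Gabra4 at 0.13 ± 0.04, none called and 3 at an unadjusted p under 0.05. Fry called both receptor lists (adjusted p = 0.049 for each), camera with the preset correlation the glutamate list (adjusted p = 0.018), and camera with an estimated correlation neither (adjusted p = 0.28). Both differences depended on scaling: glutamate genes differed by 0.028 after quantile normalization and 0.041 after median centring (exact permutation p = 0.074 and 0.093), and GABA genes by 0.021 and 0.029 (0.18 and 0.14). Without poly(I:C) 6 both receptor lists passed the exact permutation test (adjusted p = 0.045 for glutamate and 0.030 for GABA), as did newly formed oligodendrocyte markers (0.030) and immediate early genes (0.045). Htr2a, a serotonin receptor, rose (0.20 ± 0.05, adjusted p = 0.029), whereas its list of 26 dopamine and serotonin genes differed by -0.059 (exact permutation p = 0.041, adjusted 0.14; -0.0042, p = 0.89, for members at or above the 50th percentile of brightness), with the dopamine receptor genes Drd3 at -0.19 ± 0.06 and Drd1 at -0.17 ± 0.07. Drd1 and Drd2 stand in the striatal list too. Kcnv1, a potassium channel subunit, rose among 13 excitatory neuron markers (0.20 ± 0.04, adjusted p = 0.028), and that list differed by 0.047 (exact permutation p = 0.054; 0.031, p = 0.18, after quantile normalization). The calls of Gria4, Htr2a and Kcnv1 were each lost after quantile normalization and without control 2, control 3 or poly(I:C) 1, and Htr2a and Kcnv1 also without poly(I:C) 3 or poly(I:C) 4 and Htr2a without control 1, with adjusted p up to 0.0575 for Gria4, 0.0684 for Htr2a and 0.0708 for Kcnv1 over these fits.

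The interneuron, synaptic and immediate early lists had no called member in limma, with 6 interneuron, 3 presynaptic, 3 postsynaptic and 4 immediate early genes at an unadjusted p under 0.05. The differences were -0.036 for 23 interneuron genes (exact permutation p = 0.25), with Dlx1 at -0.20 ± 0.07 and Cck at 0.11 ± 0.03, 0.021 for 19 presynaptic genes (0.27), with Pclo at 0.11 ± 0.03, and 0.033 for 19 postsynaptic scaffold genes (0.10), with Dlg1 at 0.09 ± 0.03. After quantile normalization these were -0.060 (exact permutation p = 0.045, not passing after adjustment), 0.00028 (0.99) and 0.0083 (0.64). Immediate early genes, which follow recent neuronal activity, differed by 0.089 over 25 members (exact permutation p = 0.30). Npas4, an activity-dependent transcription factor, was at 6.35 ± 0.27 in controls and 7.02 ± 0.51 after poly(I:C) (SD, n = 6; limma adjusted p = 0.063). Poly(I:C) 6 lay at 6.16 and the other poly(I:C) samples between 6.83 and 7.56. Without poly(I:C) 6 the Npas4 difference was 0.84 and passed (limma adjusted p = 0.0127), and the immediate early list differed by 0.16 and passed (exact permutation, adjusted p = 0.045). Without control 4 Dlx1 passed (limma adjusted p = 0.0421). Of 16 glucocorticoid-responsive genes the metallothionein gene Mt1 fell (-0.18 ± 0.04, adjusted p = 0.017, no overlap), and the list differed by -0.014 (exact permutation p = 0.43; -0.035, p = 0.037, after quantile normalization, not passing after adjustment). Circadian clock genes differed by 0.058 (exact permutation p = 0.22), with Per2 at 0.16 ± 0.07, oxidative phosphorylation genes by 0.012 (0.53) and heat shock and unfolded protein genes by 0.015 (0.70). No member of these 3 lists passed in limma, with 4 clock genes, 0 oxidative phosphorylation genes and 1 heat shock gene at an unadjusted p under 0.05, and the last 2 lists were below 0 after quantile normalization. Oxidative phosphorylation was also below 0 without poly(I:C) 5, and heat shock without poly(I:C) 3 or poly(I:C) 4.

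Over the 28 lists, 0 passed in the exact permutation test after adjustment, 8 had an unadjusted p under 0.05 (3 higher, 5 lower; 0 higher and 10 lower after quantile normalization, 0 higher and 6 lower after median centring), camera with its preset correlation called 7, camera with an estimated correlation 0 and fry 2. The smallest p of 924 splits, 0.0022, times 28 lists exceeds the threshold, so a single list could not have passed alone.

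Sex-linked transcripts were examined gene by gene. Xist lay at 3.17 ± 0.04 in controls and 3.16 ± 0.02 after poly(I:C) (SD, n = 6), below the 25th percentile of every array, and the Y-linked genes Kdm5d, Uty and Eif2s3y were measured above it in all samples. Kdm5d differed by 0.17 ± 0.05 SE (adjusted p = 0.051; 0.0260 without control 4, 0.0111 without poly(I:C) 2 and 0.0488 with array weights) and Uty by 0.08 ± 0.03 (adjusted p = 0.23). Eif2s3y differed by 0.53 ± 0.17 (adjusted p = 0.088), with controls 1 and 5 at 5.29 and 5.31 and the other controls between 6.07 and 6.26.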

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

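The tests of other splits of the samples were laid down before their results were seen. All other tests of explanations in this part were chosen after the patterns had been seen. Of 100 splits of the 12 samples, drawn with the real one included, 1 gave as many as 653 probe sets at an adjusted p under 0.05, the real one, and the highest of the others gave 30. For the 190 probe sets at an unadjusted p under 0.05 and at least 1.2-fold the number was also 1 of 100, and the highest of the others gave 136. Chance assignment of the samples is therefore unlikely for both counts, though 100 splits do not exclude it. A shared difference in dissection, RNA preparation or array run between the groups cannot be excluded by such splits, and since the labels number the samples group by group, a run order following those numbers and the group cannot be told apart.

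The lower mean of the myelin list was weighed against dissection. Within groups the myelin score rose with the deep-layer score (Pearson r = 0.75, permutation p = 0.012, adjusted over 6 relations 0.029; Spearman rho = 0.79, permutation p = 0.016, adjusted 0.047; 12 samples). Without the 2 samples farthest from the median deep-layer score r was 0.46, so its size depends in part on those samples. It was 0.91 in the poly(I:C) samples and 0.21 in the controls (exact permutation p = 0.0097 and 0.70). With the deep-layer score as a covariate the myelin difference went from -0.22 to -0.11 ± 0.06 (SE), so less deep cortex and white matter in the dissected tissue may account for part of it and cannot be told apart from an effect of exposure with these samples. Less striatal tissue stays open too: the myelin difference was -0.20 (exact permutation p = 0.043) without controls 5 and 6 and -0.15 ± 0.09 (SE) with the striatal score as a covariate. Prenatal exposure, the difference the design names, remains an open explanation.

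For the higher means of the detained-intron and Dlk1-Dio3 lists, a larger share of unspliced or nuclear RNA predicts a higher mean of detained-intron genes as a set. A higher mean was seen in 26 of 26, of which 7 passed (exact permutation p = 0.0022 for the list, adjusted p = 0.070 in camera with an estimated correlation). That list is part of the pattern to be explained, so its rise does not test the explanation. The detained-intron and Dlk1-Dio3 scores moved together within groups (Pearson r = 0.91, permutation p = 0.00024, adjusted 0.0014; Spearman rho = 0.92, permutation p = 0.00013, adjusted 0.00078; r = 0.91 without the 2 farthest samples, 0.91 in the controls and 0.97 in the poly(I:C) samples), which a shared cause of another kind could also give. Small nucleolar RNAs, also nuclear, were lower (-0.19, 17 of 59 called lower and 2 higher). A larger share of nuclear RNA would not by itself give this, if the probe sets measured the short RNAs themselves, which is not known. A larger share of unspliced RNA remains a candidate explanation, whether it arose in the tissue or in preparation. If less deep cortex were the whole cause, the detained-intron difference would fall to near 0 with the deep-layer score as a covariate. It stayed at 0.14 ± 0.05 (SE), which argues against that cause only as far as the score tracks the dissected depth. The Dlk1-Dio3 list was not tested in this way. Genomic DNA carried into the RNA cannot be told apart: olfactory and vomeronasal receptor genes, which it would raise, differed by -0.0233 as a list, but most lie near the floor and those at or above the 50th percentile of brightness differed by 0.0356. An effect of exposure stays open.

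The lower mean of the small nucleolar RNA list (-0.19, exact permutation p = 0.0087) lay mostly in 30 box C/D RNAs, which differed by -0.29 and held 14 of its 17 lower calls, while 26 H/ACA RNAs differed by -0.077 (exact permutation p = 0.37). A larger share of nuclear RNA alone would raise these nucleolar RNAs, if the probe sets measured the short RNAs themselves, which is not known. Their fall, mostly in box C/D RNAs, could also have a cause of its own, so it does not decide. If a larger share of unspliced RNA were the cause, the list score would fall as the detained-intron score rises within groups. That relation was weak (Pearson r = -0.18, permutation p = 0.63; Spearman rho = -0.06, permutation p = 0.85; 12 samples; r = 0.59 without the 2 farthest samples, -0.59 in the controls and 0.46 in the poly(I:C) samples) and decides nothing. A loss of short RNAs during preparation stays open, since 38 short noncoding RNAs other than box C/D, the 26 H/ACA included, differed by -0.11 (exact permutation p = 0.16), which does not decide. Exposure itself stays open here too.

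Single samples far from the rest of their group were found in 26 of 346 tests of a gene or list within a group, where chance gives about 1 in 20, or 17.3. Each value below is the gap to the nearest sample as a share of the group's range. For lists, control 5 was low in small nucleolar RNA (0.749) and control 3 low in glutamate receptor genes (0.676). Control 5 was also high in Gas5 (0.731) and low in Rny1 (0.836) and Tie1 (0.762). Control 4 was high in Mir128-1 (0.658), Rims1 (0.702) and Kdm5d (0.765) and low in Dhcr7 (0.698) and Cd68 (0.770), and control 2 was low in Otx2 (0.628) and Htr2a (0.693). Poly(I:C) 4 was low in Thbs4 (0.706), Mobp (0.685), Cplx3 (0.742) and Plin4 (0.632) and high in Alas2 (0.667). Poly(I:C) 5 was high in Cldn5 (0.700), Ttr (0.661) and Jun (0.791). Poly(I:C) 1 was low in Drd2 (0.645) and Cxcl2 (0.736) and high in Ndufs1 (0.854). Poly(I:C) 2 was high in Calml4 (0.627) and low in Kdm5d (0.630), and poly(I:C) 6 was high in Sox9 (0.660). Among the 12457 probe sets to which the annotation gives no gene, left out of the report's comparison and fitted alone, 67 passed an adjusted p under 0.05, 47 higher and 20 lower.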

How the results depend on the processing

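Alternatives that left out controls 5 and 6 or used a covariate, and all settings of the added lists, were chosen after seeing the data. All 653 called probe sets, where tested, kept their direction under every alternative except the detained-intron covariate, where 648 did. The number called moved by over 1.5 times to 414 with all rows of the table and 122 without variance moderation (more rows to adjust over, and fewer degrees of freedom), and to 343 with the striatal, 48 with the deep-layer and 0 with the detained-intron covariate. On leaving out single samples it ran from 230 to 818. It fell by over 1.5 times without control 1, 2 or 3 or poly(I:C) 1, 3, 4 or 6, and never rose by as much. A covariate that differs between groups also takes up part of the group difference. At an unadjusted p under 0.05 and 1.2-fold the 190 became 124 above the 50th percentile and 1096 with all rows, and 171 to 238 on leaving out samples. Against 0 lists called, camera with its preset correlation gave 7 and fry 2, and leaving out samples 0 to 4. The myelin list kept its side of the threshold except in camera with the preset correlation (adjusted p = 3.6e-16), over alternatives with adjusted p up to 0.28, and its difference ran from -0.25 to -0.18 on leaving out samples. The olfactory and vomeronasal receptor list reversed to 0.0356 for members at or above the 50th percentile, adjusted p = 0.62, and the cause was not tested. Of 139 genes followed, 36 were called and 23 kept their call in every alternative run on them, 3 lost it with quantile normalization, 5 without controls 5 and 6 and 13 without at least 1 sample, and 0 reversed. Of the 103 not called, 27 passed in at least 1 alternative, 22 of them without at least 1 sample and 9 with the replicate block.

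Replicate numbers do not pair the samples: same-numbered samples correlated at -0.092 to 0.110 in their deviations from the group means, 1 of 6 pairs over 0.1, and 1 control and 0 poly(I:C) samples correlated best with their own number. With the replicate number as a block 536 probe sets passed, 421 of them among the 653, the 190 became 196, 0 lists passed, and the myelin list had an adjusted p of 0.22. It gave 14 myelin members called. Permutation within replicate numbers has 64 arrangements, and 0.031 is the smallest p it can give. The Dlk1-Dio3, small nucleolar RNA and detained-intron lists stood at that value (adjusted p = 0.073 each) and the olfactory and vomeronasal receptor list at an adjusted p of 0.11, so calls missing there, the 28 lists included, say nothing about stability.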

Other observations

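The tests in this part were chosen after seeing the data. Outside the Dlk1-Dio3 locus, 270 microRNA genes differed by 0.018 on average (log2; exact permutation p = 0.21; 0.081 with adjusted p = 0.042 for members at or above the 50th percentile of brightness), with 6 higher and 1 lower past the threshold. The higher ones included Mir138-2 (0.34 ± 0.08 SE), Mir181b-1 (0.29 ± 0.07) and Mir505 (0.26 ± 0.06). Among long noncoding RNAs, Malat1, which stays in the nucleus, was 0.43 ± 0.11 higher (limma adjusted p = 0.049), and Snhg11, a neuronal noncoding RNA, was 0.34 ± 0.07 higher (adjusted p = 0.021). The 7 host RNAs of small nucleolar RNAs differed by -0.066 (exact permutation p = 0.13) with Gas5 called lower and Snhg11 higher. Their mean was 0.050 when all probe sets of a gene were averaged, and the list passed without poly(I:C) 6 (-0.094, adjusted p = 0.036) and for members at or above the 50th percentile (-0.22, adjusted p = 0.015). Gas5 enters the list by its brightest probe set (-0.78), while its other probe sets differed by 0.13, 0.22 and 0.08. These passes therefore do not show a fall of host RNAs as a class. Of 76 ribosomal protein genes, 55 had a lower mean, only Rps27 passed (-0.23 ± 0.04, adjusted p = 0.013), and the list differed by -0.027 (exact permutation p = 0.087, adjusted 0.12), passing after quantile normalization (-0.046, adjusted p = 0.011) and without control 4 (-0.036, adjusted p = 0.035). Of 1157 olfactory and vomeronasal receptor genes, 6 were called lower and the list differed by -0.023 (exact permutation p = 0.013, adjusted 0.023; adjusted p = 0.070 in camera with an estimated correlation).

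The detained-intron members with the lowest p were Ogt, the enzyme that adds N-acetylglucosamine to proteins (0.18 ± 0.04), Nktr (0.24 ± 0.05), the splicing factor gene Luc7l3 (0.29 ± 0.06) and the nuclear export gene Nxf1 (0.19 ± 0.04). Controls 1, 2 and 3 scored 7.56, 7.57 and 7.55 on this list, controls 4, 5 and 6 scored 7.68, 7.72 and 7.68, and the poly(I:C) samples lay between 7.72 and 7.88. Within groups the detained-intron score was related neither to the myelin score (Pearson r = 0.07, permutation p = 0.85; Spearman rho = -0.04, permutation p = 0.91) nor to the small nucleolar RNA score (r = -0.18, permutation p = 0.63; rho = -0.06, permutation p = 0.85) beyond chance. Without the 2 farthest samples these r were 0.19 and 0.59, in the controls 0.28 and -0.59 and in the poly(I:C) samples -0.09 and 0.46. The upper-layer score fell where the myelin score rose (r = -0.71, permutation p = 0.014, adjusted 0.029; rho = -0.66, permutation p = 0.029, adjusted 0.059), with r = -0.39 without the 2 farthest samples, so the size of r depends in part on those samples. It was -0.95 in the poly(I:C) samples (exact permutation p = 0.0028, n = 6) and -0.37 in the controls (exact permutation p = 0.48, n = 6). The striatal and myelin scores gave r = 0.36 (permutation p = 0.17) and rho = 0.26 (permutation p = 0.34), with r = 0.26 without the 2 farthest samples, 0.55 in the controls and 0.40 in the poly(I:C) samples.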
